A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

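RNA of a Saccharomyces cerevisiae wine fermentation was measured on 21 one-colour Affymetrix yeast arrays, 3 biological replicates at each of 7 times of harvest. Per the labels, the authors processed the arrays with RMA in the affy package, and the deposited values are log2 probe set summaries. Neither a version nor a parameter is given for either, and it is not stated which arrays were normalized together. RMA gives all arrays processed together one distribution of values, so a change in the total mRNA of a cell cannot be seen on this scale. The values ran from 2.01 to 14.1, with nearly equal medians, which the file was checked for before use.

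The table holds 9335 probe sets. The 60 control probe sets, 2443 probe sets with no gene in the annotation supplied and 328 that match several genes were left out of the tests. Of the 6504 probe sets with 1 gene, the one with the highest mean over all 21 arrays stood for its gene, which left 5656 genes, 315 of them with several probe sets. For 14 of those 315 genes, 2 probe sets passed in opposite directions at 340 h against 24 h. Another 284 genes were measured on a probe set of a type that the maker marks as shared by similar sequences, and the text says so for the genes with the largest changes. Genes on the left-out probe sets, among them members of large families, are missing from the gene lists.

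Group means per time point were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with default settings), with the 15 arrays of 24 h to 340 h for the main study and all 21 arrays for comparisons with 1 h or 12 h. Each of 48, 60, 120 and 340 h was compared with 24 h, and successive times with each other. The tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 5656 genes of a comparison, with an adjusted p under 0.05 as the threshold. Genes that also changed at least 2-fold were counted apart. A moderated F test asked for any change over the 5 main time points. Comparisons that use the same 24 h arrays are not independent, so the number of sustained changes was set beside 100 simulations of unchanged groups that share those arrays. Values per array (ribosomal RNA controls and the difference between 3' and 5' control probe sets) were compared by exact permutation of 3 against 3 arrays, two-sided.

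Gene lists (44, with 1 more of 5 reference genes for scaling alone) were tested with limma's camera at its preset correlation between genes of 0.01, adjusted over the lists of a comparison. Each was tested again with the correlation estimated from the data, and with fry. Beside the test stand the members that passed over all genes and those that passed when adjusted over the list alone. The pattern used for cytosolic ribosomal proteins also took in RPP1, a subunit of RNase P, and that for mitochondrial ribosomal proteins took in MRP8, which is not one. RPN4, among the proteasome genes, is their transcription factor.

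The lists, the tests of the comparisons, the rule for naming genes and all alternatives but the last one below were fixed before the data were examined. The closing section says which of its own tests were chosen later. The rule names the 6 largest rises and 6 largest falls for each comparison with 24 h (3 and 3 for the others), among genes that passed and whose 3 arrays of one time all lay on one side of the other 3. It also names up to 4 members of each list described, with the largest changes, at least 1 of them in the opposite direction where one passed. A short list of well-known genes of fermentation, stress and nitrogen use was open to naming throughout. Genes in the text are S. cerevisiae symbols of the supplied annotation, or systematic names where there is no symbol.

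Replicate numbers 1 to 3 recur at every time, and the labels do not say what they mark. Whether same-numbered arrays deviate together was checked by the correlation of their deviations from the group means over all genes. Every same-numbered pair had a correlation over 0.1 only for 120 h against 60 h (lowest 0.16) and 340 h against 120 h (lowest 0.15), so only there do the data pair the arrays. All results in the text come from the fit without a block, as fixed beforehand, and the block is an alternative. The block changed no count there by more than 1.5 times: 794 genes with the replicate block against 540 without, and 2649 against 2400.

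The analysis was tested on simulated data with the spread of these arrays, where 100 of 5656 genes were changed 2-fold and another 100 were changed 4-fold in each run. For 48 h against 24 h, 74% of 2-fold and 98% of 4-fold changes were called, and 2.82% of the calls were of unchanged genes. For 60 h against 24 h these were 86%, 100% and 7.92%, for 120 h against 24 h 83%, 99% and 4.71%, and for 340 h against 24 h 84%, 100% and 4.66%. For 24 h against 12 h they were 86%, 99% and 3.14%. In the real data 21.2% (48 h) to 63.8% (340 h) of the genes passed against 24 h, so these rates need not hold there.

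Alternatives were 3 other scalings (a second quantile normalization, centring on the array median and on the reference genes), a replicate block, a filter on the lowest 20% of genes by mean, 2 other ways to use probe sets, other sets of arrays in the fit, a trend with a robust spread, other fold thresholds, and each array left out in turn. One more, with protein-coding genes alone, was chosen after seeing the data. Where an array was left out, its time point kept 2. Figures were drawn with matplotlib 3.10.9.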

Results

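The 21 Affymetrix yeast arrays cover a 15-day wine fermentation. Each of 7 time points (1, 12, 24, 48, 60, 120 and 340 h) has 3 biological replicates. The main study, per the labels, runs from 24 h (0.5% ethanol) through 48 h (2%), 60 h (3.5%) and 120 h (7%) to 340 h (10%). Values are log2 probe set signals, and 5656 genes were tested. Array medians lay between 6.62 and 6.90. With only 3 arrays per time point, the median standard error of a change was 0.20 on the log2 scale.

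Arrays of the same time point correlated across genes with a mean Pearson r of 0.970 to 0.989, where genes are not independent replicates. The time points lay along a path in the plot of principal components, with 1 h and 340 h farthest apart. The array of 24 h replicate 3 stood apart from its group: its mean r with the other 24 h arrays was 0.960, and its 18S ribosomal RNA controls read 9.33 against 6.36 and 6.49. Without it, the counts of changed genes were 1188 at 48 h, 2248 at 60 h, 2933 at 120 h and 3598 at 340 h, each within 1.5 times the count with it.

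**Figure D1:**
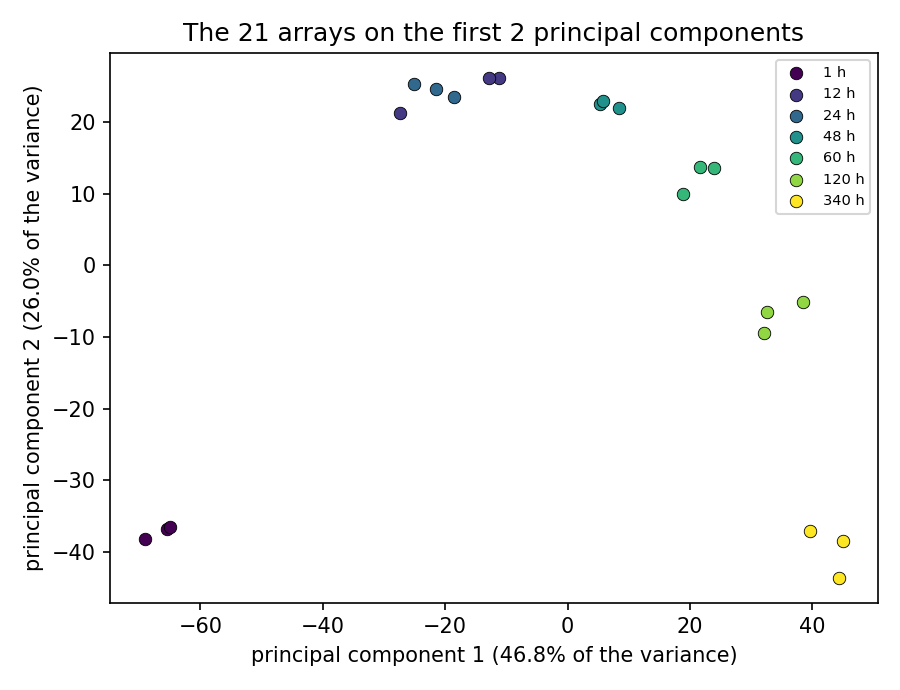
Each point is 1 of the 21 arrays, coloured by time of harvest, on the first 2 principal components of the 5656 genes (arbitrary units, with 46.8% and 26.0% of the variance). The arrays of 12 h and 24 h lie close together, and those of 48 h to 340 h follow in order of time.

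Changes below are log2 differences ± standard error from limma, with n = 3 arrays at each time point, and a gene rose or fell only where its Benjamini-Hochberg adjusted p was under 0.05. The scale is relative. Centring each array on the median of 5 reference genes shifted the median change of all genes. Against 24 h, the shift was -0.11 at 48 h, 0.11 at 60 h, 0.51 at 120 h and 1.05 at 340 h. The 5 genes' own median change was -0.21, -0.24, -0.22 and -0.60. The shift had the wrong sign at 48 h, was too small at 60 h and too large at 120 h and 340 h. Between successive times it was 0.22 (to 60 h), 0.41 (to 120 h), 0.54 (to 340 h) and -0.24 (1 h to 12 h). Centring on array medians gave shifts of 0.12 at 340 h against 24 h or 120 h and 0.10 at 12 h against 1 h. A gene marked as not on the reference genes did not pass after centring on them. No mark is given for 24 h against 12 h, where none passed.

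The comparison of 48 h (2% ethanol) with 24 h (0.5% ethanol) covers the first step of the main study. Of the lists that held with an estimated correlation between genes, those of the general stress response (adjusted p = 0.00645) and the respiratory chain (adjusted p = 0.0328) were higher, and those of tRNA synthetases (adjusted p = 0.023) and purine synthesis (adjusted p = 0.023) lower. The largest rise was that of CYB2 (3.79 ± 0.44), the mitochondrial lactate dehydrogenase, from 5.0 ± 0.97 to 8.80 ± 0.81 (mean ± SD, n = 3; limma adjusted p = 7.44e-06). It was followed by INH1 (3.42 ± 0.26), an inhibitor of the ATP synthase, QCR10 (3.18 ± 0.17) of respiratory complex III, INO1 (2.91 ± 0.26), which makes inositol phosphate, PHM8 (2.75 ± 0.25), a phosphatase, and SPI1 (2.64 ± 0.22), a cell wall protein. The 6 largest falls were all of tRNA genes, among them YNCC0010C (-2.87 ± 0.26) and YNCE0014W (-2.83 ± 0.26), on shared probe sets. Of 91 tRNA genes, 84 fell and 7 did not pass, with a median change of -1.36. Of the 91, 88 are on shared probe sets in every comparison, so their counts need not be independent.

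Of the genes that the stress regulators Msn2 and Msn4 control, 45 of 52 members rose, 0 fell and 7 did not pass (48 rose and 0 fell, adjusted over the list alone), with a median change of 1.38. The set passed upward (camera adjusted p = 4.15e-29, and adjusted p = 0.00645 with an estimated correlation). Its members CTT1 (2.38 ± 0.24), the cytosolic catalase, HSP12 (1.62 ± 0.20), ALD3 (2.55 ± 0.22) and DCS2 (2.40 ± 0.21) rose. In the respiratory chain and ATP synthase, 31 of 32 members rose, 0 fell and 1 did not pass (32 rose and 0 fell, adjusted over the list alone), with a median change of 1.45. That set also passed upward (camera adjusted p = 3.91e-24, and adjusted p = 0.0328 with an estimated correlation). Examples were COX13 (2.39 ± 0.19), COX4 (2.06 ± 0.26) and COX5A (1.96 ± 0.22). Among mitochondrial ribosomal proteins, 45 of 69 members rose, 0 fell and 24 did not pass (55 rose and 0 fell, adjusted over the list alone), with a median change of 0.64 (camera adjusted p = 9.31e-16, and adjusted p = 0.0568 with an estimated correlation). By reference centring 2 rose and 0 fell, with a median of 0.53. For the TCA cycle, 10 of 15 members rose, 0 fell and 5 did not pass (11 rose and 0 fell, adjusted over the list alone), with a median change of 0.84 (on the reference genes, 2 rose, 0 fell and the median was 0.73) (camera adjusted p = 8.81e-07, and adjusted p = 0.096 with an estimated correlation), and all 4 genes of succinate dehydrogenase rose, from SDH4 (1.67 ± 0.19) down to SDH1 (1.18 ± 0.22, not on the reference genes). Reserve carbohydrates moved likewise, but their lists share members with the Msn2/Msn4 list, among them the 4 examples named here, so these results are not independent of it. In trehalose metabolism, 6 of 9 members rose, 0 fell and 3 did not pass (8 rose and 0 fell, adjusted over the list alone), with a median change of 0.95 (camera adjusted p = 5.36e-06, and adjusted p = 0.096 with an estimated correlation). Members included TSL1 (2.12 ± 0.25) and PGM2 (1.92 ± 0.18). In glycogen metabolism, 7 of 10 members rose, 0 fell and 3 did not pass (the same counts adjusted over the list alone), with a median change of 1.34 (camera adjusted p = 3.50e-06, and adjusted p = 0.0568 with an estimated correlation). Examples were GPH1 (2.05 ± 0.28), the phosphorylase, and GSY2 (1.94 ± 0.20), the synthase.

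Among nitrogen catabolite repressed genes, which serve the use of poor nitrogen sources, 22 of 32 members rose, 0 fell and 10 did not pass (23 rose and 0 fell, adjusted over the list alone), with a median change of 1.08 (camera adjusted p = 1.97e-12, and adjusted p = 0.096 with an estimated correlation). Examples were DAL3 (2.58 ± 0.24) and DUR3 (2.56 ± 0.29) of allantoin and urea use and the permeases MEP2 (2.13 ± 0.32) and GAP1 (1.96 ± 0.31). In thiamine and pyridoxine synthesis, 6 of 14 members rose, 0 fell and 8 did not pass (8 rose and 0 fell, adjusted over the list alone), with a median change of 0.54 (camera adjusted p = 0.00162, and adjusted p = 0.096 with an estimated correlation). An example was THI4 (2.63 ± 0.24). In ribosome biogenesis, 32 of 87 members fell, 0 rose and 55 did not pass (0 rose and 51 fell, adjusted over the list alone), with a median change of -0.62 (camera adjusted p = 3.67e-13, and adjusted p = 0.241 with an estimated correlation). Of the cytosolic tRNA synthetases, 9 of 18 members fell, 0 rose and 9 did not pass (0 rose and 16 fell, adjusted over the list alone), with a median change of -0.54 (camera adjusted p = 8.81e-07, and adjusted p = 0.023 with an estimated correlation). Members included TYS1 (-1.43 ± 0.20) and VAS1 (-0.93 ± 0.18). In purine and one-carbon synthesis, 10 of 19 members fell, 0 rose and 9 did not pass (0 rose and 14 fell, adjusted over the list alone), with a median change of -0.53 (camera adjusted p = 2.19e-07, and adjusted p = 0.023 with an estimated correlation). By reference centring 0 rose and 1 fell, with a median of -0.64. Examples were IMD2 (-0.83 ± 0.17, not on the reference genes) and ADE4 (-0.82 ± 0.19, not on the reference genes). In amino acid synthesis, 25 of 63 members fell, 4 rose and 34 did not pass (4 rose and 31 fell, adjusted over the list alone), with a median change of -0.46 (camera adjusted p = 2.80e-07, and adjusted p = 0.096 with an estimated correlation). On the reference genes 0 rose and 6 fell, with a median of -0.57. ARG1 (-1.62 ± 0.30) and LEU9 (-1.21 ± 0.25) fell and SER3 (1.18 ± 0.28, not on the reference genes) rose. The anaerobic ADP/ATP carrier AAC3 (-2.48 ± 0.19) and the chaperone SSA2 (-1.96 ± 0.21) also fell.

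The test called 1199 genes at 48 h, 723 higher and 476 lower, of which 300 and 126 changed at least 2-fold. Centred on the reference genes, 397 passed, 197 higher and 200 lower, so the share higher went from 60.3% to 49.6% (at least 2-fold, 70.4% to 55.9%). Camera passed 27 of 44 lists at the preset correlation. With an estimated correlation 4 held (Msn2/Msn4, respiratory, tRNA synthetases and purines).

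**Figure D2:**
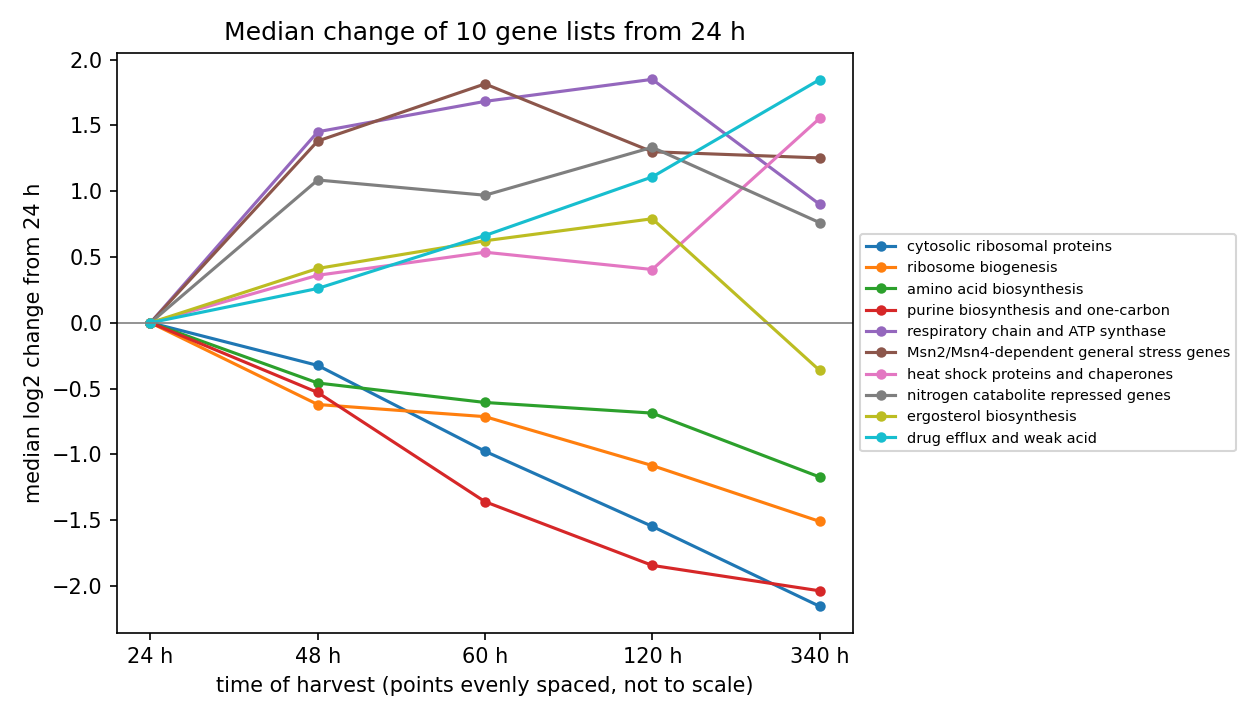
Lines give the median log2 change from 24 h of the members of 10 gene lists (y axis, log2) at 24, 48, 60, 120 and 340 h (x axis, evenly spaced). At 340 h the medians ran from -2.15 for cytosolic ribosomal proteins to 1.85 for drug efflux genes; the ergosterol list (-0.36 there) turned upward when arrays were centred on reference genes.

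The comparison of 60 h (3.5% ethanol) with 24 h covers a longer time and a higher ethanol level, which the design does not part. The general stress list was higher (adjusted p = 0.00672 with an estimated correlation) and those of purine synthesis (adjusted p = 0.00672) and tRNA synthetases (adjusted p = 0.0147) were lower. The largest rises were again those of CYB2 (5.42 ± 0.44) (limma adjusted p = 3.59e-08), INO1 (4.22 ± 0.26) and PHM8 (4.0 ± 0.25), joined by PUT4 (4.29 ± 0.34), the proline permease, BDH2 (4.03 ± 0.29), a putative medium-chain alcohol dehydrogenase, and HSP26 (3.92 ± 0.25), a small heat shock protein that went from 6.06 ± 0.53 to 9.98 ± 0.23 (mean ± SD, n = 3). The glutamine permease GNP1 (-3.63 ± 0.17) and AAC3 (-3.57 ± 0.19) had the largest falls, and the other 4 of the 6 largest were tRNA genes, among them YNCC0010C (-3.52 ± 0.26) and YNCE0014W (-3.48 ± 0.26). Of 91 tRNA genes, 89 fell. Of 57 small nucleolar RNA genes, 40 fell and 17 did not pass, with a median of -0.91, and 16 fell when centred on the reference genes.

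Of cytosolic ribosomal protein genes, 75 of 81 members fell, 0 rose and 6 did not pass (0 rose and 77 fell, adjusted over the list alone), with a median change of -0.98. The set passed downward (camera adjusted p = 6.17e-20, and adjusted p = 0.0889 with an estimated correlation). Members included RPS26B (-2.42 ± 0.24) and RPL9A (-2.25 ± 0.28). Ribosome biogenesis followed, where 50 of 87 members fell, 0 rose and 37 did not pass (0 rose and 57 fell, adjusted over the list alone), with a median change of -0.71 (camera adjusted p = 1.61e-09, and adjusted p = 0.29 with an estimated correlation). In purine and one-carbon synthesis, 18 of 19 members fell, 0 rose and 1 did not pass (the same counts adjusted over the list alone), with a median change of -1.36 (camera adjusted p = 1.08e-11, and adjusted p = 0.00672 with an estimated correlation). Examples were ADE2 (-1.98 ± 0.22), GCV1 (-1.86 ± 0.17) and ADE1 (-1.75 ± 0.25). The tRNA synthetases moved with them, where 15 of 18 members fell, 0 rose and 3 did not pass (0 rose and 16 fell, adjusted over the list alone), with a median change of -0.98 (camera adjusted p = 1.93e-07, and adjusted p = 0.0147 with an estimated correlation). Among cell cycle genes, 12 of 23 members fell, 0 rose and 11 did not pass (the same counts adjusted over the list alone), with a median change of -0.65 (camera adjusted p = 6.54e-04, and adjusted p = 0.0997 with an estimated correlation). Among them were the mitotic cyclins CLB1 (-2.02 ± 0.25) and CLB2 (-1.45 ± 0.18) and the G1 cyclin CLN2 (-1.17 ± 0.24). All 4 measured histone genes fell (camera adjusted p = 0.00897, and adjusted p = 0.104 with an estimated correlation). Members included HTB2 (-1.07 ± 0.22, not on the reference genes) and HTZ1 (-1.06 ± 0.18, not on the reference genes).

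Of Msn2/Msn4 genes, 49 of 52 members rose, 0 fell and 3 did not pass (50 rose and 0 fell, adjusted over the list alone), with a median change of 1.82 (camera adjusted p = 3.56e-24, and adjusted p = 0.00672 with an estimated correlation). Examples were CTT1 (3.17 ± 0.24), RTN2 (3.20 ± 0.26) and SPI1 (3.50 ± 0.22). In the respiratory chain, 32 of 32 members rose, 0 fell and 0 did not pass (the same counts adjusted over the list alone), with a median change of 1.68 (camera adjusted p = 1.09e-18, and adjusted p = 0.0595 with an estimated correlation). Among them were QCR10 (3.78 ± 0.17) and RIP1 (2.80 ± 0.35). Nitrogen scavenging genes followed, where 22 of 32 members rose, 2 fell and 8 did not pass (the same counts adjusted over the list alone), with a median change of 0.97 (camera adjusted p = 1.93e-07, and adjusted p = 0.114 with an estimated correlation). PUT1 (3.82 ± 0.24) of proline oxidation, GAP1 (3.67 ± 0.31) and MEP2 (3.51 ± 0.32) rose and CAR2 (-1.08 ± 0.21) of arginine use fell. Among autophagy genes, 17 of 36 members rose, 0 fell and 19 did not pass (the same counts adjusted over the list alone), with a median change of 0.51 (camera adjusted p = 1.48e-04, and adjusted p = 0.0595 with an estimated correlation). Examples were ATG39 (2.53 ± 0.22) and ATG32 (1.96 ± 0.21), the receptors for nuclear membrane and mitochondria. Vacuolar hydrolases moved alike, where 9 of 12 members rose, 0 fell and 3 did not pass (the same counts adjusted over the list alone), with a median change of 0.91 (camera adjusted p = 2.24e-04, and adjusted p = 0.0889 with an estimated correlation). An example was the protease PRB1 (1.49 ± 0.20). Of the glucose kinases, HXK2 (-2.08 ± 0.20) fell while GLK1 (1.29 ± 0.18) and HXK1 (0.91 ± 0.19) rose. The high-affinity glucose transporter HXT6 (2.18 ± 0.28) rose, on a probe set close in sequence to its neighbour HXT7, and the low-affinity HXT1 (-1.09 ± 0.25, not on the reference genes) fell.

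The 3' minus 5' difference of the SPT15 control was lower at 60 h than at 24 h (-0.40, exact permutation p = 0.1, two-sided). At 60 h 2455 genes passed, 1280 higher and 1175 lower, with 572 and 401 at least 2-fold. Centred on the reference genes, 1295 passed, and the share higher went from 52.1% to 67.3% (at least 2-fold, 58.8% to 69.9%). Camera passed 30 of 44 lists, and 3 held with an estimated correlation (Msn2/Msn4, tRNA synthetases and purines).

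The comparison of 120 h (7% ethanol) with 24 h covers the change up to late in the fermentation. The Msn2/Msn4 stress list stayed higher (adjusted p = 0.0438 with an estimated correlation), while purine genes (adjusted p = 0.0129) and tRNA synthetases (adjusted p = 0.0172) were lower. CYB2 (5.88 ± 0.44) (limma adjusted p = 7.40e-09), INO1 (5.11 ± 0.26), PUT4 (4.64 ± 0.34) and PHM8 (4.44 ± 0.25) stayed among the largest rises, with HSP30 (4.52 ± 0.24), a plasma membrane stress protein, and HPA2 (4.49 ± 0.33), a histone acetyltransferase. HSP30 went from 4.94 ± 0.31 to 9.46 ± 0.52 (mean ± SD, n = 3). The largest falls were those of LYS9 (-3.98 ± 0.23) of lysine synthesis, GNP1 (-3.82 ± 0.17), AIM20 (-3.54 ± 0.17), AAC3 (-3.51 ± 0.19), the hexokinase HXK2 (-3.38 ± 0.20) and the ribosomal protein gene RPS26B (-3.35 ± 0.24).

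Of cytosolic ribosomal protein genes, 80 of 81 members fell, 1 rose and 0 did not pass (the same counts adjusted over the list alone), with a median change of -1.55 (camera adjusted p = 1.37e-26, and adjusted p = 0.0594 with an estimated correlation). RPL7A (-3.20 ± 0.20) and RPL9A (-3.12 ± 0.28) fell and RPL15B (0.74 ± 0.22) rose (adjusted p = 0.0568 without 120 h replicate 1). Ribosome biogenesis moved with them: 68 of 87 members fell, 1 rose and 18 did not pass (the same counts adjusted over the list alone), with a median change of -1.09 (camera adjusted p = 3.37e-12, and adjusted p = 0.256 with an estimated correlation). The member that rose was NOP16 (0.64 ± 0.24), which lost its call without 24 h replicate 1 (adjusted p = 0.0757), 24 h replicate 3 (0.101) or 120 h replicate 1 (0.211). All 19 measured purine and one-carbon genes fell (the same adjusted over the list alone), with a median change of -1.84. The camera adjusted p was 3.16e-11, and 0.0129 with an estimated correlation. Examples were GCV1 (-2.91 ± 0.17) and ADE17 (-2.41 ± 0.20). Of cytosolic tRNA synthetases, 17 of 18 members fell, 0 rose and 1 did not pass (the same counts adjusted over the list alone), with a median change of -1.26 (camera adjusted p = 7.76e-08, and adjusted p = 0.0172 with an estimated correlation). Among them were TYS1 (-2.54 ± 0.20) and FRS1 (-1.88 ± 0.18). In amino acid synthesis, 42 of 63 members fell, 6 rose and 15 did not pass (the same counts adjusted over the list alone), with a median change of -0.69 (camera adjusted p = 4.52e-06, and adjusted p = 0.157 with an estimated correlation). By reference centring 6 rose and 12 fell, with a median of -0.17. LYS12 (-2.65 ± 0.15) and SHM2 (-2.54 ± 0.18) fell and SHM1 (1.51 ± 0.17) rose.

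Among drug efflux and weak acid genes, 19 of 23 members rose, 0 fell and 4 did not pass (the same counts adjusted over the list alone), with a median change of 1.11 (camera adjusted p = 4.02e-07, and adjusted p = 0.157 with an estimated correlation). Examples were the transporters PDR15 (3.12 ± 0.34) and RSB1 (3.64 ± 0.31) beside SPI1 and HSP30. Respiratory genes were higher too, where 31 of 32 members rose, 0 fell and 1 did not pass (the same counts adjusted over the list alone), with a median change of 1.85 (camera adjusted p = 4.09e-13, and adjusted p = 0.111 with an estimated correlation). Among them were CYC1 (3.16 ± 0.32), cytochrome c, and QCR10 (3.96 ± 0.17). Of Msn2/Msn4 genes, 45 of 52 members rose, 1 fell and 6 did not pass (the same counts adjusted over the list alone), with a median change of 1.30 (camera adjusted p = 4.09e-13, and adjusted p = 0.0438 with an estimated correlation), and the member that fell was GPD1 (-0.83 ± 0.19, not on the reference genes), a glycerol phosphate dehydrogenase. In gluconeogenesis and the glyoxylate cycle, 9 of 13 members rose, 0 fell and 4 did not pass (the same counts adjusted over the list alone), with a median change of 1.12 (camera adjusted p = 0.00217, and adjusted p = 0.167 with an estimated correlation). Members included ACS1 (2.21 ± 0.16) and FBP1 (2.14 ± 0.25). Among genes of fatty acid oxidation and peroxisomes, 14 of 29 members rose, 0 fell and 15 did not pass (the same counts adjusted over the list alone), with a median change of 0.51 (camera adjusted p = 3.22e-04, and adjusted p = 0.146 with an estimated correlation). Examples were the carnitine carrier CRC1 (3.16 ± 0.20) and the catalase CTA1 (2.61 ± 0.23). In ergosterol synthesis, 18 of 24 members rose, 0 fell and 6 did not pass (the same counts adjusted over the list alone), with a median change of 0.79 (camera adjusted p = 1.54e-04, and adjusted p = 0.232 with an estimated correlation). Among them were ERG8 (1.77 ± 0.22) and HMG1 (1.71 ± 0.26). Nitrogen scavenging genes were also higher, where 21 of 32 members rose, 2 fell and 9 did not pass (21 rose and 4 fell, adjusted over the list alone), with a median change of 1.33 (camera adjusted p = 1.24e-05, and adjusted p = 0.212 with an estimated correlation). MEP2 (3.96 ± 0.32) rose and the peptide transporter OPT2 (-1.18 ± 0.32, not on the reference genes) fell.

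Hexose transporter genes went both ways and their list did not pass: HXT6 (2.53 ± 0.28) rose and HXT1 (-3.17 ± 0.25) fell. At 120 h 3008 genes passed, 1504 higher and 1504 lower, with 774 and 703 at least 2-fold. Centred on the reference genes, 82.7% of the genes that passed were higher, against 50% (at least 2-fold, 83.5% against 52.4%). Camera passed 24 of 44 lists, and 3 held with an estimated correlation (Msn2/Msn4, tRNA synthetases and purines).

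The comparison of 340 h (10% ethanol) with 24 h spans the whole main study. The lists of tRNA synthetases (adjusted p = 0.0337 with an estimated correlation) and purine synthesis (adjusted p = 0.0337) were lower, and ribosomal protein genes made up 4 of the 6 largest falls. HSP30 (6.06 ± 0.24) had the largest rise, from 4.94 ± 0.31 to 11 ± 0.12 (mean ± SD, n = 3; limma adjusted p = 1.65e-12). Next came GAC1 (5.54 ± 0.21), which targets a phosphatase to glycogen synthase, INO1 (5.33 ± 0.26) and the U1 spliceosomal RNA SNR19 (5.31 ± 0.20). They were followed by the ribosomal RNA gene RDN18-1 (5.24 ± 0.98), on a shared probe set, and the small nucleolar RNA SNR45 (5.11 ± 0.47). The largest falls were those of RPL13A (-4.67 ± 0.18), RPL7B (-4.47 ± 0.21), RPL7A (-4.40 ± 0.20) and RPS28B (-4.22 ± 0.21), of which the last 3 sit on shared probe sets, then HXK2 (-3.94 ± 0.20) and SAM4 (-3.78 ± 0.18), a homocysteine methyltransferase.

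Of cytosolic ribosomal protein genes, 80 of 81 members fell, 0 rose and 1 did not pass (the same counts adjusted over the list alone), with a median change of -2.15 (camera adjusted p = 6.90e-24, and adjusted p = 0.0812 with an estimated correlation). In ribosome biogenesis, 74 of 87 members fell, 4 rose and 9 did not pass (the same counts adjusted over the list alone), with a median change of -1.51 (camera adjusted p = 6.91e-10, and adjusted p = 0.395 with an estimated correlation). NOP1 (-3.07 ± 0.20) and NOP56 (-2.78 ± 0.23) fell and IMP4 (1.21 ± 0.25) rose. Purine and one-carbon genes were lower, where 17 of 19 members fell, 0 rose and 2 did not pass (the same counts adjusted over the list alone), with a median change of -2.04 (camera adjusted p = 1.96e-07, and adjusted p = 0.0337 with an estimated correlation). Among them were GCV1 (-3.30 ± 0.17) and SHM2 (-3.09 ± 0.18). So were the tRNA synthetases, where 17 of 18 members fell, 0 rose and 1 did not pass (the same counts adjusted over the list alone), with a median change of -2.02 (camera adjusted p = 5.87e-07, and adjusted p = 0.0337 with an estimated correlation). Members included TYS1 (-3.24 ± 0.20) and WRS1 (-2.88 ± 0.19). In amino acid synthesis, 46 of 63 members fell, 3 rose and 14 did not pass (3 rose and 47 fell, adjusted over the list alone), with a median change of -1.17 (camera adjusted p = 1.96e-07, and adjusted p = 0.136 with an estimated correlation). By reference centring 16 rose and 17 fell, with a median of -0.12. LYS9 (-3.47 ± 0.23) and LYS12 (-3.19 ± 0.15) fell and CPA1 (1.37 ± 0.15) rose.

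Among heat shock proteins and chaperones, 23 of 28 members rose, 1 fell and 4 did not pass (the same counts adjusted over the list alone), with a median change of 1.55 (camera adjusted p = 1.54e-08, and adjusted p = 0.0911 with an estimated correlation). HSP26 (4.83 ± 0.25), BTN2 (3.05 ± 0.22), SSA4 (2.26 ± 0.18) and HSP104 (2.16 ± 0.19) rose and SSA2 (-1.36 ± 0.21, not on the reference genes) fell. For drug efflux and weak acid genes, 19 of 23 members rose, 0 fell and 4 did not pass (the same counts adjusted over the list alone), with a median change of 1.85 (camera adjusted p = 1.54e-08, and adjusted p = 0.136 with an estimated correlation). Members included PDR15 (4.24 ± 0.34), RSB1 (4.05 ± 0.31) and SPI1 (4.77 ± 0.22). Msn2/Msn4 genes were higher as well, where 41 of 52 members rose, 0 fell and 11 did not pass (42 rose and 0 fell, adjusted over the list alone), with a median change of 1.25 (camera adjusted p = 8.70e-12, and adjusted p = 0.0589 with an estimated correlation). Examples were XBP1 (3.57 ± 0.18), a repressor made under stress, and TSL1 (3.38 ± 0.25). In trehalose metabolism, 7 of 9 members rose, 0 fell and 2 did not pass (7 rose and 1 fell, adjusted over the list alone), with a median change of 1.72 (camera adjusted p = 0.00178, and adjusted p = 0.271 with an estimated correlation). Among them were TPS2 (2.36 ± 0.31) and TPS1 (1.84 ± 0.22). In nitrogen scavenging, 19 of 32 members rose, 4 fell and 9 did not pass (the same counts adjusted over the list alone), with a median change of 0.76 (camera adjusted p = 2.02e-04, and adjusted p = 0.315 with an estimated correlation). MEP2 (4.71 ± 0.32) and its activator GAT1 (4.70 ± 0.27) rose and OPT2 (-1.26 ± 0.32, not on the reference genes) fell. In the respiratory chain, 20 of 32 members rose, 7 fell and 5 did not pass (21 rose and 7 fell, adjusted over the list alone), with a median change of 0.90 (camera adjusted p = 0.00178, and adjusted p = 0.433 with an estimated correlation). CYC1 (2.31 ± 0.32) rose and ATP5 (-1.34 ± 0.23, not on the reference genes) fell. Among single genes of sugar transport and fermentation, HXT6 (3.31 ± 0.28), GLK1 (1.67 ± 0.18) and PDC1 (0.52 ± 0.17) rose, while HXT1 (-2.42 ± 0.25), TDH3 (-1.28 ± 0.15, not on the reference genes) and ENO2 (-2.04 ± 0.27, not on the reference genes) fell.

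Among 57 small nucleolar RNA genes, 43 rose, 1 fell and 13 did not pass, with a median of 1.43, and all 4 spliceosomal RNA genes rose, with a median of 5.02. Of 91 tRNA genes, 57 fell, 5 rose and 29 did not pass, with a median of -0.99. Centred on the reference genes, 32 rose and 14 fell. The 18S ribosomal RNA controls read 11.4 at 340 h against 7.39 at 24 h (difference 3.99, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 arrays allow). The difference between 3' and 5' probe sets of ACT1, a sign of RNA degradation, was higher at 340 h by 0.63 (exact permutation p = 0.3, two-sided), or by 0.29 without 340 h replicate 2. For the SPT15 control it was higher by 0.71 (exact permutation p = 0.1, two-sided), and for SRB4 lower by 0.19 (p = 0.7).

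At 340 h 3609 genes passed, 1571 higher and 2038 lower, with 955 and 1163 at least 2-fold. Centred on the reference genes, 89.3% of the genes that passed were higher, against 43.5% (at least 2-fold, 91.3% against 45.1%). Camera passed 19 of 44 lists, and 2 held with an estimated correlation (tRNA synthetases and purines).

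**Figure D3:**
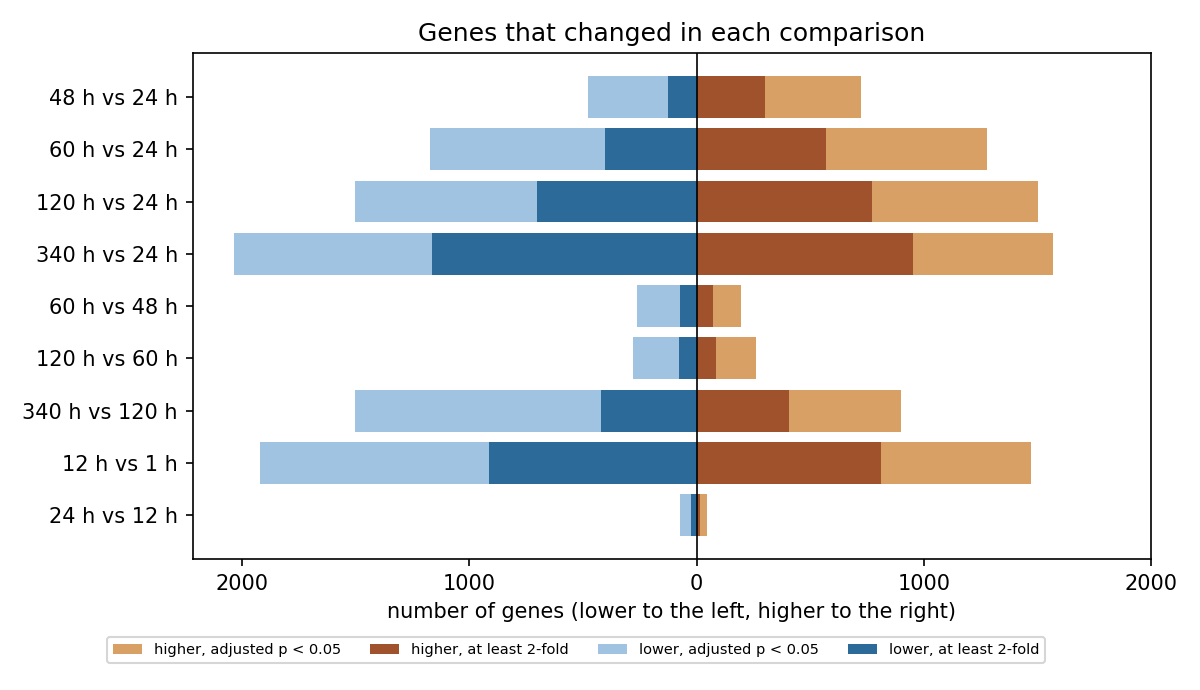
Bars give the number of genes (x axis) higher, to the right, or lower, to the left, in each of the 9 comparisons (y axis); light bars count genes with an adjusted p under 0.05 and dark bars those that also changed at least 2-fold. Totals ran from 117 genes (24 h against 12 h) to 3609 (340 h against 24 h); when arrays were centred on reference genes, most genes that passed at 340 h were higher (89.3%).

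Across the 5 main time points, limma's moderated F test called 4175 of 5656 genes. Sustained changes, at least 2-fold in the same direction at all 4 later times, were found for 170 genes higher and 77 lower. Independent lists of those sizes would share 0.701 and 0.228 genes, and simulated unchanged groups sharing the 24 h arrays gave at most 0 in 100 runs. With no gene changed in the simulation, the adjustment alone holds its counts near 0. Neither figure can therefore show how far shared error of the 24 h arrays adds to the real counts. The 4 comparisons use the same 24 h arrays, so their calls are not independent. Sustained rises included CYB2, QCR10, INO1, PHM8, SPI1, HSP26, MEP2, TSL1 and PDR15. Sustained falls included GNP1 and AAC3. Of the 77 lower, 44 were tRNA genes and 33 protein-coding. Centred on the reference genes, 41 were lower.

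**Figure D4:**
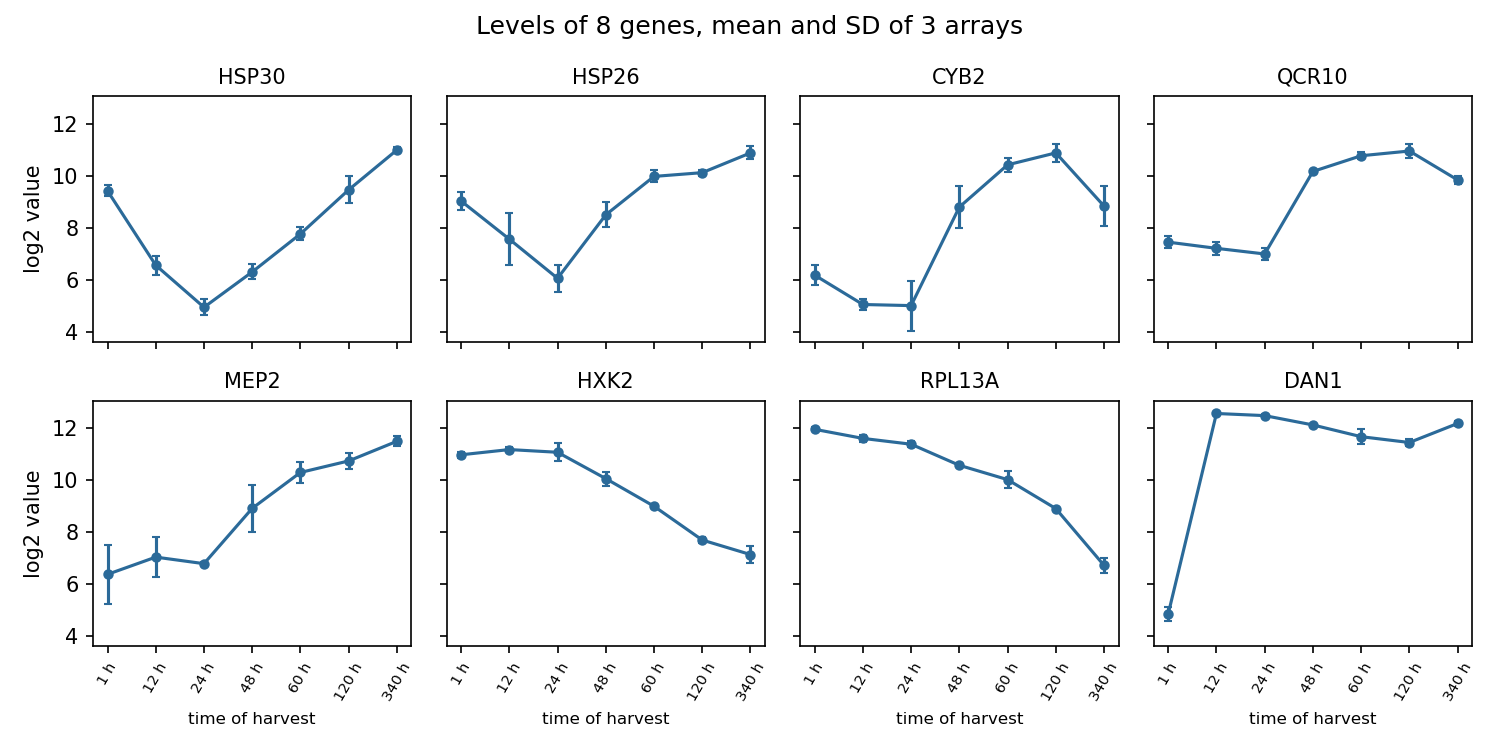
Points are means of 3 arrays and bars are SD (y axis, log2 value) for 8 genes over the 7 times of harvest (x axis, evenly spaced). HSP30, HSP26 and MEP2 rose from 24 h to 340 h (changes of 6.06, 4.83 and 4.71), HXK2 and RPL13A fell (-3.94 and -4.67), CYB2 and QCR10 had their highest mean at 120 h, and DAN1 rose by 7.72 from 1 h to 12 h.

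The steps between successive times ask when each change came. From 48 h to 60 h, UGA4 (3.14 ± 0.34), a GABA permease on a shared probe set, PUT4 (3.00 ± 0.34) and BSC1 (2.80 ± 0.54) had the largest rises (limma adjusted p = 5.31e-05 for PUT4), and BAP3 (-1.98 ± 0.26), an amino acid permease, PHO3 (-1.84 ± 0.29, not on the reference genes), an acid phosphatase, and CWP1 (-1.76 ± 0.29, not on the reference genes) of the cell wall the largest falls. Of cytosolic ribosomal protein genes, 31 of 81 members fell, 0 rose and 50 did not pass (0 rose and 64 fell, adjusted over the list alone), with a median change of -0.60 (camera adjusted p = 1.29e-26, and adjusted p = 0.0564 with an estimated correlation). On the reference genes 0 rose and 0 fell, with a median of -0.38. Those that fell included RPS26B (-1.28 ± 0.24, not on the reference genes) and RPL17B (-1.14 ± 0.18, not on the reference genes). In purine and one-carbon synthesis, 13 of 19 members fell, 0 rose and 6 did not pass (0 rose and 15 fell, adjusted over the list alone), with a median change of -0.72 (camera adjusted p = 1.11e-13, and adjusted p = 0.00505 with an estimated correlation). By reference centring 0 rose and 0 fell, with a median of -0.50. Members included SHM2 (-1.26 ± 0.18, not on the reference genes) and GCV1 (-1.11 ± 0.17, not on the reference genes). Among cell cycle genes, 7 of 23 members fell, 0 rose and 16 did not pass (0 rose and 12 fell, adjusted over the list alone), with a median change of -0.52 (camera adjusted p = 3.08e-07, and adjusted p = 0.0564 with an estimated correlation). By reference centring 0 rose and 1 fell, with a median of -0.30. Examples were the G1 cyclins CLN2 (-1.53 ± 0.24) and CLN1 (-1.41 ± 0.19, not on the reference genes). Of Msn2/Msn4 genes, 14 of 52 members rose, 0 fell and 38 did not pass (19 rose and 0 fell, adjusted over the list alone), with a median change of 0.45 (camera adjusted p = 4.91e-10, and adjusted p = 0.0564 with an estimated correlation). On the reference genes 4 rose and 0 fell, with a median of 0.66. An example was GND2 (1.24 ± 0.19). Of single genes of nitrogen use, PUT1 (2.22 ± 0.24) and GAP1 (1.71 ± 0.31) rose and DAL7 (-1.74 ± 0.32) fell. The 3' minus 5' difference was lower at 60 h than at 48 h for the ACT1 control (-0.72) and the SPT15 control (-0.59), each with an exact permutation p = 0.1, two-sided. In this step 457 genes passed, 197 higher and 260 lower, with 73 and 74 at least 2-fold, and 123 passed when centred on the reference genes (90.2% higher, against 43.1%; at least 2-fold, 89.8% against 49.7%). The count without 1 array was 291, 238 and 223 (without 48 h replicates 1, 2 and 3), 189 and 250 (without 60 h replicates 1 and 2) and 316 (without 60 h replicate 3), and it was 837 with the 6 arrays fitted alone. Camera passed 22 of 44 lists and 1, purines, held with an estimated correlation.

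From 60 h to 120 h, the small nucleolar RNAs SNR45 (4.20 ± 0.47) and SNR13 (2.76 ± 0.26) and the gene YDL012C (2.07 ± 0.18) had the largest rises (limma adjusted p = 8.95e-06 for SNR13), and the low-affinity glucose transporter HXT1 (-2.08 ± 0.25), the biotin gene BIO3 (-2.01 ± 0.22) and YJR154W (-1.97 ± 0.43) the largest falls. Of cytosolic ribosomal protein genes, 37 of 81 members fell, 0 rose and 44 did not pass (0 rose and 58 fell, adjusted over the list alone), with a median change of -0.61 (camera adjusted p = 8.81e-26, and adjusted p = 0.133 with an estimated correlation). By reference centring 0 rose and 2 fell, with a median of -0.20. Those that fell included RPL9B (-1.76 ± 0.21) and RPS28B (-1.58 ± 0.21). Of Msn2/Msn4 genes, 15 of 52 members fell, 1 rose and 36 did not pass (3 rose and 19 fell, adjusted over the list alone), with a median change of -0.26, though the median was 0.14 when centred on the reference genes (camera adjusted p = 3.21e-05, and adjusted p = 0.278 with an estimated correlation). RTN2 (-1.94 ± 0.26), ALD3 (-1.81 ± 0.22) and HSP12 (-1.71 ± 0.20) fell and DDR2 (1.10 ± 0.21) rose. Among drug efflux and weak acid genes, 7 of 23 members rose, 0 fell and 16 did not pass (11 rose and 0 fell, adjusted over the list alone), with a median change of 0.58 (camera adjusted p = 4.15e-07, and adjusted p = 0.278 with an estimated correlation). Those that rose included HSP30 (1.70 ± 0.24) and the polyamine exporter TPO2 (1.46 ± 0.21). In purine and one-carbon synthesis, 7 of 19 members fell, 0 rose and 12 did not pass (0 rose and 10 fell, adjusted over the list alone), with a median change of -0.43 (camera adjusted p = 7.41e-05, and adjusted p = 0.133 with an estimated correlation). By reference centring 0 rose and 0 fell, with a median of -0.02. Of glycerol genes, STL1 (-1.42 ± 0.15) and GPD1 (-0.88 ± 0.19, not on the reference genes) fell and the channel FPS1 (0.96 ± 0.16) rose. The 3' minus 5' difference of ACT1 was higher at 120 h by 0.49 (exact permutation p = 0.1, two-sided), and that of SRB4 lower by 0.16 (p = 0.7). In this step 540 genes passed, 260 higher and 280 lower, with 87 and 77 at least 2-fold; without 60 h replicate 1 or 2 the count was 312 or 358. Centred on the reference genes 313 passed (94.9% higher, against 48.1%), and 282 at least 2-fold (94.7% higher, against 53.0%). Camera passed 8 of 44 lists, and 0 held with an estimated correlation (6 at an unadjusted p under 0.05), while the fry test passed 11.

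From 120 h to 340 h, the largest rises were those of RDN18-1 (5.05 ± 0.98), SNR3 (4.99 ± 0.26) and the U5 RNA SNR7-L (4.65 ± 0.17), of which the first and last are on shared probe sets, and the largest falls those of the arginine permease ALP1 (-2.91 ± 0.22), the flavohemoglobin YHB1 (-2.88 ± 0.28), on a shared probe set, and the mitochondrial superoxide dismutase SOD2 (-2.85 ± 0.27) (limma adjusted p = 3.79e-07 for SOD2). Of 57 small nucleolar RNA genes 51 rose, and of 91 tRNA genes 78 rose, while the 18S ribosomal RNA controls were higher by 3.53 (exact permutation p = 0.1, two-sided). Among heat shock proteins, 20 of 28 members rose, 0 fell and 8 did not pass (21 rose and 0 fell, adjusted over the list alone), with a median change of 1.06 (camera adjusted p = 1.87e-11, and adjusted p = 0.155 with an estimated correlation). Members included the co-chaperones SIS1 (2.80 ± 0.23) and BTN2 (3.41 ± 0.22) and the Hsp70 gene SSA4 (1.90 ± 0.18). In ergosterol synthesis, 22 of 24 members fell, 0 rose and 2 did not pass (1 rose and 23 fell, adjusted over the list alone), with a median change of -1.30 (camera adjusted p = 2.51e-08, and adjusted p = 0.622 with an estimated correlation). Examples were ERG13 (-1.98 ± 0.21), ERG20 (-1.78 ± 0.20) and MVD1 (-1.86 ± 0.21). In the respiratory chain, 24 of 32 members fell, 0 rose and 8 did not pass (the same counts adjusted over the list alone), with a median change of -1.12 (camera adjusted p = 3.93e-07, and adjusted p = 0.622 with an estimated correlation). Among them were ATP20 (-2.08 ± 0.20) and COX4 (-1.82 ± 0.26). Among mitochondrial ribosomal proteins, 40 of 69 members fell, 0 rose and 29 did not pass (0 rose and 41 fell, adjusted over the list alone), with a median change of -0.55 (camera adjusted p = 1.26e-05, and adjusted p = 0.622 with an estimated correlation). On the reference genes 2 rose and 4 fell, with a median of -0.01. An example was MRPL6 (-1.51 ± 0.26).

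The cytosolic catalase CTT1 (-2.05 ± 0.24) fell. Cytosolic ribosomal proteins fell further, where 46 of 81 members fell, 1 rose and 34 did not pass (1 rose and 48 fell, adjusted over the list alone), with a median change of -0.58 (camera adjusted p = 3.93e-07, and adjusted p = 0.622 with an estimated correlation). By reference centring 2 rose and 7 fell, with a median of -0.04. RPL13A (-2.19 ± 0.18) and RPS0B (-2.0 ± 0.17) fell. RPS9A (0.69 ± 0.23) rose, but not without 120 h replicate 2 (adjusted p = 0.101), 340 h replicate 1 (0.0858) or 340 h replicate 3 (0.0518). In amino acid synthesis, 31 of 63 members fell, 4 rose and 28 did not pass (4 rose and 33 fell, adjusted over the list alone), with a median change of -0.54, though 6 rose and 2 fell when centred on the reference genes (camera adjusted p = 0.00401, and adjusted p = 0.622 with an estimated correlation). SHM1 (-1.74 ± 0.17) and ARG4 (-1.56 ± 0.21) fell and LEU9 (1.35 ± 0.25) rose. Among drug efflux and weak acid genes, 10 of 23 members rose, 0 fell and 13 did not pass (the same counts adjusted over the list alone), with a median change of 0.37 (camera adjusted p = 7.94e-04, and adjusted p = 0.622 with an estimated correlation). Those that rose included TPO2 (1.59 ± 0.21) and AQR1 (1.80 ± 0.30). The 3' minus 5' difference of SPT15 was higher at 340 h by 0.86 (exact permutation p = 0.1, two-sided). In this step 2400 genes passed, 898 higher and 1502 lower, with 406 and 422 at least 2-fold. The share higher was 37.4%, and it became 89.7% of 1431 genes when centred on the reference genes, and 48.4% when centred on the array median. At least 2-fold, it was 49.0%, and it became 92.3% on the reference genes, 62.1% on the array median and 60.0% after quantile normalization. Camera passed 9 of 44 lists, and 0 held with an estimated correlation (3 at an unadjusted p under 0.05), while the fry test passed 17.

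The labels include 1 h and 12 h for completeness, outside the main study. From 1 h to 12 h, the lists of anaerobic growth (adjusted p = 0.00423 with an estimated correlation) and purine synthesis (adjusted p = 0.00959) were higher and that of iron uptake (adjusted p = 0.00876) lower. The cell wall mannoprotein gene DAN1 (7.72 ± 0.16) had the largest rise, from 4.84 ± 0.28 to 12.56 ± 0.06 (mean ± SD, n = 3; limma adjusted p = 2.36e-20), before the seripauperins PAU15 (6.35 ± 0.31) and PAU19 (6.12 ± 0.33), on shared probe sets. The largest falls were those of ANS1 (-7.54 ± 0.27), the phosphate transporter PHO84 (-5.99 ± 0.24) and YMR244W (-5.58 ± 0.23). Among hypoxic and anaerobic genes, 19 of 23 members rose, 0 fell and 4 did not pass (the same counts adjusted over the list alone), with a median change of 3.01 (camera adjusted p = 2.77e-14, and adjusted p = 0.00423 with an estimated correlation). Examples were TIR4 (4.62 ± 0.24), HES1 (4.55 ± 0.15) and AAC3 (4.37 ± 0.21). All 10 measured seripauperins rose (the same adjusted over the list alone), with a median change of 5.47. The camera adjusted p was 1.60e-12, and 0.184 with an estimated correlation. In sulfate assimilation and methionine synthesis, 18 of 26 members rose, 3 fell and 5 did not pass (the same counts adjusted over the list alone), with a median change of 2.54 (camera adjusted p = 2.61e-08, and adjusted p = 0.117 with an estimated correlation). MET3 (4.47 ± 0.20) and MET6 (4.20 ± 0.17) rose and SAM4 (-1.39 ± 0.21) fell. In purine and one-carbon synthesis, 14 of 19 members rose, 3 fell and 2 did not pass (15 rose and 3 fell, adjusted over the list alone), with a median change of 2.27 (camera adjusted p = 2.87e-06, and adjusted p = 0.00959 with an estimated correlation). ADE17 (5.29 ± 0.18) and ADE3 (4.08 ± 0.14) rose and GUA1 (-1.62 ± 0.18) fell. Amino acid synthesis followed, where 37 of 63 members rose, 13 fell and 13 did not pass (37 rose and 14 fell, adjusted over the list alone), with a median change of 0.64 (camera adjusted p = 1.12e-04, and adjusted p = 0.219 with an estimated correlation). HIS4 (4.07 ± 0.21) and ARG1 (3.68 ± 0.31) rose and ARO7 (-1.38 ± 0.20) fell. For the TCA cycle, 14 of 15 members rose, 0 fell and 1 did not pass (the same counts adjusted over the list alone), with a median change of 1.23 (camera adjusted p = 6.36e-06, and adjusted p = 0.219 with an estimated correlation). An example was ACO1 (2.47 ± 0.22).

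Glycolytic genes rose, where 11 of 16 members rose, 0 fell and 5 did not pass (the same counts adjusted over the list alone), with a median change of 1.15 (camera adjusted p = 9.00e-05, and adjusted p = 0.228 with an estimated correlation). Members included HXK1 (2.97 ± 0.23), GLK1 (2.49 ± 0.22) and PGK1 (2.17 ± 0.17). In ergosterol synthesis, 19 of 24 members rose, 0 fell and 5 did not pass (the same counts adjusted over the list alone), with a median change of 1.23 (camera adjusted p = 2.97e-06, and adjusted p = 0.219 with an estimated correlation). An example was ERG28 (2.22 ± 0.16). Every measured gene of ribosome biogenesis fell, where 87 of 87 members fell, 0 rose and 0 did not pass (the same counts adjusted over the list alone), with a median change of -2.01 (camera adjusted p = 1.58e-23, and adjusted p = 0.219 with an estimated correlation). Among them were MAK5 (-2.84 ± 0.30) and ENP2 (-2.75 ± 0.25). All 23 RNA polymerase I and III genes did likewise (the same adjusted over the list alone), with a median change of -1.50. The camera adjusted p was 4.13e-07, and 0.219 with an estimated correlation. In the iron regulon, 17 of 25 members fell, 3 rose and 5 did not pass (the same counts adjusted over the list alone), with a median change of -0.89 (camera adjusted p = 1.35e-04, and adjusted p = 0.00876 with an estimated correlation). The siderophore carriers ARN1 (-4.24 ± 0.21) and SIT1 (-4.21 ± 0.19) fell and the vacuolar metal transporter COT1 (0.55 ± 0.15, not on the reference genes) rose. The acid phosphatase PHO5 (3.99 ± 0.24) rose. The 3' minus 5' difference at 12 h was lower for ACT1 (-0.39) and SRB4 (-0.29), each with an exact permutation p = 0.1, two-sided, and higher for SPT15 (0.46, p = 0.2). Here 3393 genes passed, 1473 higher and 1920 lower, with 812 and 913 at least 2-fold, and the share higher was 43.4%, or 29.6% when centred on the reference genes (at least 2-fold, 47.1% and 31.5%). Camera passed 21 of 44 lists, and 3 held with an estimated correlation (hypoxic, purine and iron lists).

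From 12 h to 24 h few genes changed. The plasma membrane stress protein gene HSP30 (-1.62 ± 0.24) fell (limma adjusted p = 7.66e-04), as did GTT1 (-1.34 ± 0.24), a glutathione transferase, and GRE1 (-1.74 ± 0.31), a hydrophilin (adjusted p = 0.0519 without 24 h replicate 2). YGK1 (1.33 ± 0.32), YBR242W (1.29 ± 0.26) and the tRNA gene YNCD0009W (1.24 ± 0.29), on a shared probe set, had the largest rises and YNR064C (-1.62 ± 0.41) the third largest fall. Each of these 4 lost its call when some single arrays were left out. For YGK1 these were 12 h replicates 2 and 3 and 24 h replicates 1 and 2 (adjusted p = 0.107, 0.0748, 0.109 and 0.116), and for YBR242W 12 h replicate 3 and 24 h replicate 2 (0.0501 and 0.0575). For YNCD0009W they were 12 h replicate 1 and 24 h replicates 2 and 3 (0.107, 0.0817 and 0.0724), and for YNR064C 12 h replicate 1 and every 24 h replicate (0.113, 0.0682, 0.0694 and 0.14). Of Msn2/Msn4 genes, 5 of 52 members fell, 0 rose and 47 did not pass (0 rose and 13 fell, adjusted over the list alone), with a median change of -0.46 (camera adjusted p = 1.04e-09, and adjusted p = 0.192 with an estimated correlation). Among heat shock proteins, 4 of 28 members fell, 0 rose and 24 did not pass (0 rose and 7 fell, adjusted over the list alone), with a median change of -0.23 (camera adjusted p = 1.22e-05, and adjusted p = 0.192 with an estimated correlation). For oxidative stress defence, 4 of 33 members fell, 0 rose and 29 did not pass (0 rose and 9 fell, adjusted over the list alone), with a median change of -0.31 (camera adjusted p = 3.60e-06, and adjusted p = 0.192 with an estimated correlation). The 3' minus 5' difference of ACT1 was higher at 24 h by 0.65 (exact permutation p = 0.1, two-sided), or by 0.35 without 24 h replicate 3. In this comparison 117 genes passed, 45 higher and 72 lower, with 16 and 25 at least 2-fold. The limma count was 0 when centred on the reference genes and 0 with the 6 arrays fitted alone, where 410 and 780 genes had an unadjusted p under 0.05. It was 59 and 52 without 12 h replicates 2 and 3 and 22 without 24 h replicate 2, where 17 changed at least 2-fold against 41 with all arrays. It was 43 over every non-control probe set. Camera passed 11 of 44 lists (17 without 12 h replicate 1), and 0 held with an estimated correlation (3 at an unadjusted p under 0.05), while the fry test passed 3.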

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

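All tests of the small RNAs below were chosen only after the result was seen, while the splits of the arrays and the test of 24 h replicate 3 were planned.

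Probe sets outside the gene tests changed too. Between 24 h and 340 h, 308 of the 2443 probe sets with no gene in the annotation passed with at least a 2-fold change, 254 higher and 54 lower. Of the 328 probe sets that match several genes, 122 did so, 49 higher and 73 lower. The 18S ribosomal RNA controls were higher by 3.99 at 340 h (exact permutation p = 0.1, two-sided, the smallest possible), against differences of -0.28 at 48 h, -0.99 at 60 h and 0.46 at 120 h. These rest on 24 h replicate 3, and without it they were 0.68, -0.03 and 1.43, and 4.96 at 340 h.

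Small nucleolar and spliceosomal RNAs were higher at 340 h than at 24 h: of all 61, 47 rose, 1 fell and 13 did not pass, with a median change of 1.57. Each test was run on all 61, on the 34 with a mean of at least 6 at 24 h and on the 27 with such a mean before 340 h, each with and without 24 h replicate 3. A lower share of mRNA in the RNA would lift them all by one factor, but the SD among their changes was 1.49 against a median standard error of 0.25 over all 61 (1.40 to 1.58 in all choices, against at most 0.30), which argues against it as the whole cause. Carry-over of ribosomal RNA would act between arrays of one time as well, and there its slope gave -0.481% of the rise of all 61 (upper 95% limit 29.7%). Among the 34 it gave 27.5% (upper limit 56.5%), so carry-over stays open. The slope of RNA degradation gave 15.2% (upper limit 29.4%) read from the 3' minus 5' difference of ACT1 and 12.8% (upper limit 29.1%) from that of SPT15, which was higher at 340 h by 0.71. The highest upper limits over the choices were 49.0% and 34.5%. Error in these measures lowers such slopes and their limits, so degradation also stays open. No group of the design tests a biological explanation. A change in how these RNAs or the tRNAs were primed and labelled stays open.

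The array of 24 h replicate 3 stood apart from the other 24 h arrays, with a mean correlation of 0.960 with them and 0.956 with the 12 h arrays. Its 18S reading (9.33) lay within the 12 h range (8.69 to 9.69), but its 3' minus 5' differences of ACT1 (2.02) and SRB4 (2.03) lay above those of the other 24 h arrays (at most 1.25 and 1.54) and the 12 h arrays (at most 0.90 and 1.36). If it were an array of 12 h, it would lie nearer to 12 h on most of the 110 genes that differ between the other 24 h arrays and 12 h, and it lay nearer to 24 h on 48.2% of them. The values lie between the 2 times, so an array of 12 h under a 24 h label cannot be told apart from a correct label by this test. Without the array 110 genes passed between 12 h and 24 h, against 117 with it.

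For the splits, the arrays of each pair of times were divided into 3 and 3 in all 10 ways. These are too few for a share under 0.05, since the real split alone (1 of 10) is 10%. The real value and the highest of the other splits were 1199 and 0 genes for 48 h against 24 h, 2455 and 2 for 60 h, 3008 and 0 for 120 h and 3609 and 1 for 340 h, each against 24 h. They were 457 and 1 for 60 h against 48 h, 3393 and 3 for 12 h against 1 h, and 117 and 10 for 24 h against 12 h. For the 2 comparisons that passed the check for pairing, they were 540 and 0 (120 h against 60 h) and 2400 and 0 (340 h against 120 h). There, 3 of the other splits part all 3 pairs, like the real one, and 6 part 1 pair, and all of them gave 0 genes by limma. For the F test, 1 of 100 regroupings of the 15 arrays, the real one, gave as many genes (4175, highest other 1349), so chance is excluded at 0.05.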

How the results depend on the processing

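The count with protein-coding genes alone was chosen only after the result was seen; the other alternatives were planned. Of the 265 gene results named, 0 turned direction under any alternative, and all kept their call under the replicate block, centring on the array median, the mean of a gene's probe sets and the robust trend. Centring on the reference genes ended the call of 31, the 6 arrays alone that of 8, every probe set that of 4, the second quantile normalization and the fit on all arrays that of 1 each, and leaving out 1 array that of 8. Of the 83 list results described, all kept their side of the threshold under the block and with each array left out. With fry 2 lists passed that camera did not, and with an estimated correlation 64 of 83 no longer passed.

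Centred on the reference genes, counts were 397 (48 h against 24 h), 1295 (60 h against 24 h), 123 (60 h against 48 h), 313 (120 h against 60 h, 282 at least 2-fold), 1431 (340 h against 120 h) and 0 (24 h against 12 h, 0 at least 2-fold; 410 at an unadjusted p under 0.05 by limma), and 41 genes were lower at all later times. The reference genes are only 5, so each array's shift adds their own spread to every gene. The cause of these differences was not tested. With the 6 arrays alone, counts were 837 (60 h against 48 h) and 0 (24 h against 12 h, 0 at least 2-fold; 780 at an unadjusted p under 0.05 by limma), and the cause was not tested. Over every probe set they were 43 (24 h against 12 h, 23 at least 2-fold), where more tests are adjusted for, and 221 at least 2-fold (60 h against 48 h), where genes with several probe sets count more than once. Of protein-coding genes alone, 33 were lower at all later times, since the other 44 were tRNA genes.

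By construction, a 1.5-fold threshold gave more genes and a test against 2-fold (limma treat) fewer. Against 24 h these were 1049 and 82 (48 h), 2066 and 297 (60 h), 2562 and 578 (120 h) and 3221 and 1062 (340 h). For the other comparisons they were 432 and 2 (60 h against 48 h), 504 and 4 (120 h against 60 h), 2004 and 161 (340 h against 120 h), 2928 and 781 (12 h against 1 h) and 117 and 0 (24 h against 12 h, with 5 at an unadjusted p under 0.05 by treat). Higher at all later times were 370 and 26 genes, and lower 287 and 25.

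Numbers of lists with an estimated correlation were 4, 3, 3 and 2 (48, 60, 120 and 340 h against 24 h), 1 (60 h against 48 h), 0 (120 h against 60 h; 6 at an unadjusted p under 0.05 by camera), 0 (340 h against 120 h; 3), 3 (12 h against 1 h) and 0 (24 h against 12 h; 3), and the cause was not tested. With fry, which tests each list without the other genes, they were 37 (120 h against 24 h), 38 (340 h against 24 h), 17 (340 h against 120 h) and 3 (24 h against 12 h).

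With 1 array left out, counts ran from 189 to 316 (60 h against 48 h), 312 to 462 (120 h against 60 h), and 22 to 110 (24 h against 12 h, 17 to 53 at least 2-fold, 9 to 17 lists), where fewer arrays are tested. The lowest gene counts came without 60 h replicate 1 in the first 2 and without 24 h replicate 2 in the third, and the lowest number of lists without 12 h replicate 2 or 24 h replicate 1. The other counts stayed within 1.5 times, such as 802 to 1188 (48 h against 24 h) and 3391 to 3598 (340 h against 24 h).

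For the comparisons where the arrays share only a number, the replicate block gave 1462 genes (48 h), 2713 (60 h), 3207 (120 h) and 3750 (340 h against 24 h), 646 (60 h against 48 h), 3460 (12 h against 1 h) and 185 (24 h against 12 h, against 117), 4357 by the F test, and 170 and 77 sustained. The last of the pairwise counts is beyond 1.5 times, and the cause was not tested. In those 7 comparisons, in the order above, 2, 0, 2, 2, 1, 0 and 0 of 3 arrays correlated best with the array of their own number. The block changed no other call of a named gene or described list, and the number of lists past the test went from 11 to 15 (24 h against 12 h), 30 to 31 (60 h against 24 h), 22 to 21 (60 h against 48 h), 8 to 9 (120 h against 60 h) and 21 to 20 (12 h against 1 h). The arrays carry no separate background value, so how far dim genes sit above background was not analysed here; without the lowest 20% of genes all counts stayed within 1.5 times.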

Other observations

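The test of the respiratory pattern in the last paragraph was chosen only after the result was seen. Further gene groups changed against 24 h, beyond those described above. At 60 h, among genes of oxidative stress defence, 21 of 33 members rose, 5 fell and 7 did not pass (the same counts adjusted over the list alone), with a median change of 0.73 (camera adjusted p = 4.78e-05, and adjusted p = 0.0997 with an estimated correlation). The superoxide dismutase SOD2 (2.59 ± 0.27) and the peroxidase GPX1 (2.29 ± 0.16) rose and the glutathione synthase GSH2 (-1.20 ± 0.18) fell. Glycogen genes rose, where 7 of 10 members rose, 0 fell and 3 did not pass (the same counts adjusted over the list alone), with a median change of 1.94 (camera adjusted p = 1.50e-04, and adjusted p = 0.0889 with an estimated correlation). Members included the branching enzyme GLC3 (2.91 ± 0.24) and the phosphatase subunit GAC1 (2.53 ± 0.21). In DNA replication, 18 of 38 members fell, 1 rose and 19 did not pass (the same counts adjusted over the list alone), with a median change of -0.41 (camera adjusted p = 9.94e-04, and adjusted p = 0.189 with an estimated correlation). By reference centring 1 rose and 4 fell, with a median of -0.31. The clamp POL30 (-1.65 ± 0.24) and the ribonucleotide reductase RNR2 (-1.19 ± 0.21) fell and the helicase subunit MCM3 (0.91 ± 0.23) rose. Aldehyde dehydrogenases and acetyl-CoA synthetases were higher, where 5 of 7 members rose, 0 fell and 2 did not pass (the same counts adjusted over the list alone), with a median change of 1.19 (camera adjusted p = 0.00275, and adjusted p = 0.0889 with an estimated correlation). Among them were ALD4 (2.11 ± 0.24) and ACS1 (1.5 ± 0.16).

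At 340 h, among autophagy genes, 18 of 36 members rose, 3 fell and 15 did not pass (the same counts adjusted over the list alone), with a median change of 0.46 (camera adjusted p = 0.00178, and adjusted p = 0.111 with an estimated correlation). The kinase ATG1 (3.82 ± 0.31) and the conjugated protein ATG8 (2.56 ± 0.25) rose and ATG27 (-1.10 ± 0.17, not on the reference genes) fell. Several lists did not pass camera there. In glycolysis 4 of 16 members rose and 4 fell (camera adjusted p = 0.878), or 11 and 1 when centred on the reference genes, and the list passed with fry (adjusted p = 0.0319). Among cell wall genes 10 of 33 rose and 11 fell (camera adjusted p = 0.467), or 21 and 1 on the reference genes, and the list passed with fry (adjusted p = 0.0102), with the glucan synthase GSC2 (3.59 ± 0.19) up and the chitin synthase CHS2 (-1.79 ± 0.24) down. Of genes for esters and higher alcohols, which give wine its aroma, 5 of 15 rose and 4 fell (camera adjusted p = 0.878), or 9 and 2 on the reference genes, with the decarboxylase ARO10 (2.32 ± 0.28) up and the transaminase ARO8 (-2.46 ± 0.19) down.

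Of respiratory chain genes, 31 of 32 rose from 24 h to 120 h (camera adjusted p = 0.111 with an estimated correlation), and 1 hypothesis was tested. A return of air to the must would lower the anaerobic genes: of the rise from 1 h to 24 h of 29 hypoxic and seripauperin genes, a median of 94.0% was still there at 120 h, but 4 genes (AAC3 19.5%, EUG1 38.8%, ANB1 43.1% and HEM14 48.8%, chosen after their values were seen) had less than 50% left, so it stays open. Glucose was not measured in these files, and the genes it represses were already among the lists above and give no separate test, so release from glucose repression stays open. An effect of ethanol was not tested.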
